A study of Mus musculus with 12 samples.

How the data were processed

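RNA-seq data of 6 libraries of mouse Th1 cells were used, 3 controls and 3 labelled Sdhc cKO, grouped by their titles; the 6 samples of the other groups of the series were not analysed here. RNA was taken from sorted cells and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. STAR, HTSeq and DESeq2 are named, with the build mm10, in the submitters' processing notes; their versions, settings and annotation, and the strand setting of the counting, are not given in the sources used here. Nothing in the labels says whether the replicates were separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries of a group differed in sex-linked transcripts, so not all of them are repeats of the same cells.

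The deposited table holds 1 signal value per gene and library for 18929 gene symbols. The values are reads divided by a size factor: in each library 100% of them were whole multiples of the smallest value above 0, to within 0.01 of a whole number. The recovered reads summed to 18144933 to 21983821 per library, and size factors recomputed from them by the median-ratio method of DESeq2 were 0.909 to 1.11, the same as those in the table. The scaling moved the median log2 fold change of all genes by little, to -0.01 as deposited, 0.00163 with TMM, 0.03 with upper-quartile factors and -0.00626 with library totals. Of the symbols, 17613 were found in GENCODE M21 (GRCm38, the same assembly as mm10), from which positions were taken, and 22 symbols of the table had the form of a date and were left as they stood. Reads of ribosomal type on Gm26917 and Gm26924 made up 7.96% to 9.93% of a library and mitochondrial genes 0.525% to 0.888%.

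The groups, the tests, 37 gene lists, the rule for named genes and most of the settings tried in turn were fixed before the data were examined. The plan was edgeR on raw counts or, for normalized values, limma-trend; as the deposited values are normalized, limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1) was the main test. Genes with a value over 10 in at least 3 libraries were tested, 12699 in all, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and SE is the moderated standard error. Gene lists with at least 5 tested members, 31 of the 37, were tested with camera (preset inter-gene correlation 0.01), and beside it with an estimated correlation and with fry. With an estimated correlation, camera uses the residual degrees of freedom of the fit: 4 on genotype alone, 3 with the covariate and fewer with the block. A list can then fail even where its members are not correlated. The lists cover T helper lineages and effector functions, activation, cell cycle, mitochondrial and metabolic pathways, stress responses, T cell identity, ribosomal proteins, other cell types and sex-linked genes. Single genes and sums were also compared by 2-sided exact permutation tests, which with 3 against 3 cannot go below 0.1.

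Named genes were those of complex II, and among called genes without overlap between the groups and with a mean of at least 50 normalised counts, the 10 largest rises and 10 largest falls, leaving out unnamed models and antigen receptor segments. To these came up to 3 called members of each list in each direction, or the 2 most abundant members where none was called, and 13 fixed genes. As the test on genotype alone called 0 genes, the rule for called genes was applied to the fit with a covariate.

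Replicate numbers are shared by the groups. Deviations of same-numbered libraries from their group means correlated across genes at 0.579, 0.458 and 0.188 for numbers 1, 2 and 3. cKO 3 correlated better with control 2 (0.272) than with control 3. Each same-numbered value was over 0.1. Deviations of 3 libraries from their mean sum to 0 at each gene, so these values depend on each other and do not establish the pairing. The labels do not give it either. A pairing by number was thus an assumption. The fit with the replicate number as a block is given beside results whose call it changes. Settings fixed in advance were other scalings, other filters (none, or a value of 50), DESeq2 1.42.0 and limma-voom on recovered reads, array weights, pseudocounts of 0.1 and 5, the block, and each library left out in turn. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood, TMM) on recovered reads and a numeric covariate for the sex-linked transcripts: the reads on Ddx3y, Kdm5d, Uty and Eif2s3y over all counted reads, relative to the highest library, or the level of Xist, linear or log2, in its place. edgeR called 0 genes without and 670 with the covariate.

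The fits were tested on simulated data, with counts drawn from the means and depths of these libraries and 200 genes changed. The spread of each gene came from the fit with genotype and the Y-linked share, and genes were drawn independently. The simulation thus meets the terms of the covariate fit and cannot show how far its calls hold in the real data. With the trend on the Y-linked share kept in the simulation, the fit on genotype alone recovered 56% of genes changed 1.5-fold and 92% of those changed 2-fold, with 1 unchanged gene called. The fit with the covariate recovered 84% and 100%, with 13 unchanged genes called, over 12542 genes tested. Without the trend, over 12552 genes, the fit on genotype alone recovered 86% and 99% with 13 unchanged genes called, and the fit with the covariate 82% and 96% with 21. Figures were drawn with matplotlib 3.10.9.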

Results

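T cells of C57BL/6 mice were held for 5 days in culture conditions that drive T helper 1 (Th1) differentiation, and RNA from sorted cells was sequenced. The comparison took 3 control libraries of wild-type genotype and 3 libraries labelled Sdhc cKO. Sdhc encodes the C subunit of succinate dehydrogenase, complex II of the respiratory chain, which also oxidises succinate in the TCA cycle; cKO stands for a conditional knockout. The values are gene counts divided by 1 size factor per library, called normalised counts here. The control libraries held 20815668, 20137111 and 18272998 counted reads and the cKO libraries 19294857, 21983821 and 18144933. Between 17022 and 17383 genes had at least 1 read in a library. The series has 12 samples in 5 groups, and the 6 samples of the other 3 groups were not analysed here. Its title names mitochondrial metabolism, T cell differentiation and T cell function as the subject, so the comparison asks which transcripts of Th1 cells differ when complex II is targeted.

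The targeted gene was only slightly lower in the cKO libraries. Sdhc (chromosome 1, 171127165 to 171150603, minus strand, GRCm38) had normalised counts of 1683, 1602 and 1892 in the controls and 1452, 1562 and 1655 in the cKO libraries. The means were 1726 ± 149 and 1556 ± 102 (SD, n = 3 each), a log2 fold change of -0.15 (SE 0.09, 95% interval -0.36 to 0.06). The difference did not pass the test (limma adjusted p = 0.978), and the 2-sided exact permutation p was 0.2, where 0.1 is the smallest that 3 against 3 allows. Counts per gene do not resolve exons, so a deletion of part of the gene would not be seen in them, and they do not check the labels. Of the other subunits, Sdha had a log2 fold change of -0.06 (SE 0.07), Sdhb -0.13 (SE 0.08) and Sdhd -0.20 (SE 0.09), with a limma adjusted p of 0.978 for each. Over the complex II list, 5 of 6 tested genes had negative fold changes, the median was -0.09, and the list did not pass (camera adjusted p = 0.139).

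**Figure D1:**
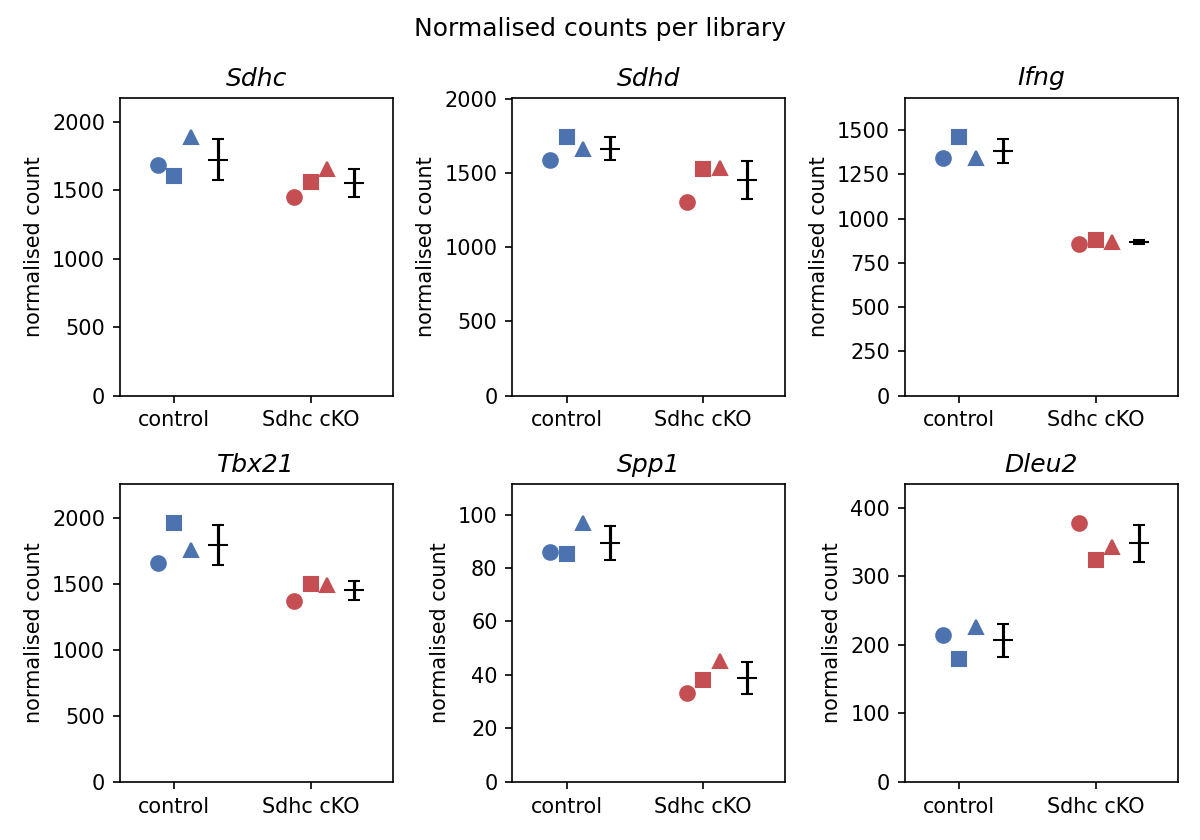
Normalised counts (vertical axes, linear, from 0) of 6 genes in the 3 control libraries (blue) and the 3 libraries labelled Sdhc cKO (red); circles, squares and triangles are replicates 1, 2 and 3, and the black bar is the mean with its SD. The Ifng values of the cKO libraries, 858, 880 and 865, lie below all control values, while the Sdhc values of the groups overlap.

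Ifng, the signature cytokine of Th1 cells, stood out in the comparison. Its normalised counts (chromosome 10, 118441046 to 118445892, plus strand) were 1342, 1461 and 1342 in the controls and 858, 880 and 865 in the cKO libraries. The means of 1382 ± 68.9 and 868 ± 11.5 (SD, n = 3 each) put the cKO level at 62.8% of control, a log2 fold change of -0.67 (SE 0.07, 95% interval -0.84 to -0.50). Tbx21, the gene of the Th1-specifying transcription factor T-bet, had means of 1794 ± 154 and 1454 ± 72.1, a log2 fold change of -0.30 (SE 0.09). Each of these 2 genes was lower in all 3 cKO libraries than in any control, with an exact permutation p of 0.1, the smallest possible. Ifng did not pass the threshold of 0.05 over all genes (limma adjusted p = 0.265) and neither did Tbx21 (0.978). With the replicate number as a block, Ifng passed (limma adjusted p = 0.0255). It also passed with DESeq2 on the recovered reads (adjusted p = 7.43e-07) and with array weights in limma (adjusted p = 0.0481). On genotype alone it did not pass with edgeR under any scaling (adjusted p = 0.219 to 0.261) or with limma-voom (adjusted p = 0.305). Nor did it pass with the other filters, the other pseudocounts or any library left out.

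Other Th1 genes showed no such separation. Gzmb, a cytotoxic granule protease, had a log2 fold change of -0.10 (SE 0.31), Tnf 0.05 (SE 0.19), the IL-12 receptor gene Il12rb2 0.04 (SE 0.10), Stat4 0.03 (SE 0.13) and the chemokine receptor gene Cxcr3 -0.21 (SE 0.20). Il2 was at the floor, with at most 3.92 normalised counts in any of the 6 libraries. Of the 29 tested genes of the Th1 effector list, 26 had negative fold changes and the median was -0.18; 0 passed over all genes, and 1, Ifng, passed when adjusted over the list alone. The list lay lower than the other tested genes by camera with its preset correlation (adjusted p = 7.13e-05), and this was lost with the correlation estimated from the data (adjusted p = 0.229 with an estimated correlation). The estimate was -0.017, below the preset 0.01, so correlated members do not account for the loss. That form of camera also uses only 4 residual degrees of freedom. By fry, which asks whether the members of a list move one way, its adjusted p was 0.048. Genes of the list for gamma delta T cells, which can also make interferon gamma, were lower in sum. The sums were 313, 274 and 337 normalised counts in the controls and 246, 198 and 175 in the cKO libraries (exact permutation p = 0.1, the smallest possible). Most of each sum came from Tcrg-C1, Tcrg-C2 and Tcrg-C4. Sox13 was lower too, with means of 28.0 in control and 18.5 in cKO. Trdv4 was at the floor, and so was Cd163l1, whose values overlapped between the groups with means of 3.41 and 5.81. As it rests mostly on the Tcrg-C genes, the sum does not show whether gamma delta T cells were fewer. The NK cell genes Klrk1 and Klrd1 had log2 fold changes of -0.58 (SE 0.53) and -0.39 (SE 0.29); their groups overlapped, but both genes and the sum of the NK cell genes were lower in cKO in all 3 pairs of same-numbered libraries. Neither passed with the replicate block (limma adjusted p = 0.269 and 0.414). With no filter on low values, the gamma delta T cell and NK cell lists were lower by camera (adjusted p = 0.00236 and 0.0261; adjusted p = 0.396 and 0.643 with an estimated correlation). Whether other cells account for part of the Ifng difference was not tested.

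Over all genes, 0 of 12699 tested genes passed (limma, adjusted p threshold 0.05), with 445 at an unadjusted p under 0.05, where 635 would be expected by chance; with the replicate block it was 1596. edgeR on the recovered reads also called 0, with 455 at an unadjusted p under 0.05. DESeq2 called 3 genes: Ifng and Spp1 were lower and Dleu2 was higher in cKO. With the replicate block limma called 1 gene, Ifng, and with array weights 1, again Ifng. Spp1 encodes osteopontin, a secreted protein, and had 89.4 ± 6.42 normalised counts in control and 38.8 ± 6.07 in cKO (SD, n = 3 each), a log2 fold change of -1.19 (SE 0.19). Dleu2, a long non-coding RNA, had 207 ± 24.2 and 348 ± 27.1, a log2 fold change of 0.75 (SE 0.13). These 2 genes were picked here because DESeq2 called them, after their values were seen. The groups did not overlap at 1289 genes, 573 with all 3 cKO values above and 716 with all below the controls, which is 10.15% of the tested genes against 10% by chance.

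Genes of T cell activation and immune checkpoints lay lower as a list. Of 25 tested members 22 had negative fold changes, with a median of -0.21 and 0 genes past the test over all genes or over the list alone (camera adjusted p = 5.72e-05; adjusted p = 0.332 with an estimated correlation). The co-stimulatory receptor gene Icos had means of 3916 ± 103 and 3444 ± 342, a log2 fold change of -0.19 (SE 0.09), and Myc, a driver of cell growth, 3474 ± 439 and 2866 ± 335, a log2 fold change of -0.28 (SE 0.12). Among genes of other T helper fates no list passed. The Th2 lineage list, to which Gata3 (log2 fold change 0.09, SE 0.08) belongs, had a camera adjusted p of 0.845. It was 0.354 for the Th17 lineage list, with a median of -0.22, and 0.479 for the Treg lineage list, with a median of -0.12, where 1 gene, Itgae, was higher when adjusted over the list alone. Without control 3 the Th17 list passed (median -0.40, adjusted p = 0.0457). The naive and memory list lay higher, with 15 of 21 positive fold changes and a median of 0.06 (camera adjusted p = 0.0233; adjusted p = 0.525 with an estimated correlation). That call ended without control 1 (adjusted p = 0.0555), control 3 (0.266) or cKO 2 (0.382).

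Genes of DNA replication and of nucleotide synthesis lay lower together, by small amounts. All 35 tested S phase genes had negative fold changes, with a median of -0.17 (camera adjusted p = 7.89e-09), as did all 20 nucleotide synthesis genes, with a median of -0.18 (camera adjusted p = 5.36e-05). The adjusted p was 0.786 and 0.821 with an estimated correlation, and the correlation among members was 0.677 and 0.828. No member passed over all genes or over its list alone. The ribonucleotide reductase gene Rrm1 had a log2 fold change of -0.15 (SE 0.14) and Rrm2 -0.07 (SE 0.11). Without cKO 1 the nucleotide list no longer passed (median -0.06, camera adjusted p = 0.207). The G2/M list showed no shift (median -0.02, camera adjusted p = 0.995), and its member Mki67, a proliferation marker, had means of 15880 ± 1580 and 15558 ± 1008.

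Mitochondrial genes shifted little. The TCA cycle list, whose genes encode the enzymes of the cycle in which complex II takes part, had 16 of 19 negative fold changes and a median of -0.10 (camera adjusted p = 0.00147; adjusted p = 0.251 with an estimated correlation). Its estimated correlation was -0.031, so correlated members do not account for the loss of that call. Its member Cs, the citrate synthase gene, had a log2 fold change of -0.04 (SE 0.07). The list of complexes III to V had 30 of 35 negative fold changes and a median of -0.09 (camera adjusted p = 0.00189; adjusted p = 0.821 with an estimated correlation), a call that ended without control 3 (median -0.04, adjusted p = 0.634). Complex I (median -0.02, camera adjusted p = 0.354) and the mitochondrially encoded genes (median -0.10, adjusted p = 0.433) did not pass with all libraries. Complex I was lower without control 1 (adjusted p = 0.0167) and with array weights (0.0262), and the mitochondrially encoded genes were lower without cKO 3 (median -0.32, adjusted p = 1.88e-05) or control 2 (-0.30, 0.0498). The list of mitochondrial transport and shuttles, which holds Slc25a1 and Slc25a11, did not pass either (median -0.10, camera adjusted p = 0.0745), but passed without cKO 1 (median -0.09, adjusted p = 0.016), with no filter on low values (-0.11, 0.039) and with array weights (-0.10, 0.0481). Glycolysis genes had a median of -0.13 (camera adjusted p = 0.558), targets of the hypoxia-inducible factor HIF -0.12 (0.397) and mitochondrial chaperones and proteases -0.08 (0.0897). With the replicate block these 3 lists passed, at camera adjusted p of 0.00844, 0.0229 and 0.025 with the preset correlation, and did not with an estimated correlation (0.630, 0.787 and 0.579). Without cKO 1 the glycolysis and HIF lists turned round, to medians of 0.14 (adjusted p = 0.0205) and 0.18 (0.00138), and without control 2 their medians were 0.04 and 0.03 (0.354 and 0.397). Without control 1 they were lower (adjusted p = 0.00862 and 0.00273), as without cKO 2 (0.0346 and 0.00148), and so were the chaperones (0.0322 without control 1 and 0.0237 without cKO 2). Hif1a itself had means of 13827 ± 356 and 12027 ± 405, a log2 fold change of -0.20 (SE 0.07, limma adjusted p = 0.978).

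Of the stress responses fixed as lists, 2 lay lower. The ATF4 response, which supplies amino acids under mitochondrial and other stress, had 27 of 31 negative fold changes and a median of -0.17 (camera adjusted p = 0.0118; adjusted p = 0.940 with an estimated correlation). Targets of NRF2, the oxidative stress regulator, had 16 of 18 negative fold changes and a median of -0.16 (camera adjusted p = 0.018; adjusted p = 0.886 with an estimated correlation). Both calls ended without cKO 1, with medians of 0.02 and 0.03, and also without control 2 (adjusted p = 0.215 and 0.102) or control 3 (0.324 and 0.266). The ATF4 call also ended under the stricter filter (adjusted p = 0.0978) and the NRF2 call with array weights (0.0537). Atf4 had a log2 fold change of -0.22 (SE 0.22). The ribosomal protein list lay higher by a median of 0.05 (camera adjusted p = 0.0198; adjusted p = 0.940 with an estimated correlation), which turned to -0.03 without cKO 1 and ended without control 2 (adjusted p = 0.606). The interferon response list lay higher by a median of 0.02 (camera adjusted p = 0.036; adjusted p = 0.525 with an estimated correlation), a call that ended without control 1, control 3, cKO 2 or cKO 3 (adjusted p = 0.249, 0.135, 0.382 and 0.0653). With no filter on low values, the 3 lists called higher no longer passed (interferon response 0.184, naive and memory 0.0854, ribosomal protein 0.082), and 11 of 36 lists were called lower, 9 of them among the 31 and 2, NK cell and gamma delta T cell, too small to test with the filter. Cholesterol synthesis (median -0.05, adjusted p = 0.354), fatty acid synthesis (-0.01, 0.779), p53 targets (-3.47e-06, 0.845), STAT5 and IL-2 signalling (-0.00, 0.845) and immediate early genes (-0.06, 0.503) did not pass with all libraries. Of these, cholesterol synthesis was lower without cKO 1 (median -0.18, adjusted p = 3.87e-05) or control 2 (-0.15, 0.000321), p53 targets were higher without cKO 1 (adjusted p = 0.0115) and immediate early genes were lower without control 1 (0.0132).

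Markers of other cell types were low beside those of T cells. Within the 3 pairs of same-numbered libraries, the sums of NK cell and gamma delta T cell genes were lower in cKO in all 3 and the sum of B cell genes was higher in all 3, while the myeloid, dendritic, CD8, granulocyte and erythroid sums went both ways. The T cell identity genes did not shift (median 0.02, camera adjusted p = 0.354), and Cd4 had means of 10507 ± 417 and 10905 ± 196. Summed normalised counts of the 2 CD8 T cell genes ran from 235 to 547 per library, of the B cell genes, mostly Ighm, from 1713 to 2165, of the myeloid genes from 109 to 210, and of the NK cell genes from 113 to 417. The granulocyte genes summed to at most 75.3 and the erythroid and platelet genes to at most 155. Of the lists large enough to test, B cell (median 0.15, camera adjusted p = 0.354) and dendritic cell and MHC II (median -0.03, camera adjusted p = 0.576) did not pass. The sum of the gamma delta T cell genes was lower in cKO, as given with the Th1 genes. Their member Tcrg-C1 had means of 71.3 ± 5.24 and 46.6 ± 4.85, a log2 fold change of -0.61 (SE 0.18, limma adjusted p = 0.978).

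The libraries differed in sex-linked transcripts across the groups. The sex-linked list did not pass (median 0.77, camera adjusted p = 0.845), and it passed with the replicate block (0.0229; adjusted p = 0.579 with an estimated correlation). Reads on the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y made up 0.048, 131 and 55.1 RPM (reads scaled to a common library size) in controls 1, 2 and 3 and 0.207, 193 and 189 RPM in cKO 1, 2 and 3. Xist, the RNA of the inactive X chromosome, had 9780, 2490 and 6406 normalised counts in the controls and 7565, 0 and 2.15 in the cKO libraries. Control 2 and control 3 thus held both kinds of transcript. The first principal component, with 49.07% of the variance, set control 1 and cKO 1 apart from the other 4 libraries. Malat1, a nuclear non-coding RNA, had 17762, 13109 and 16525 normalised counts in the controls and 40089, 20397 and 24600 in the cKO libraries, all above the controls (log2 fold change 0.80, SE 0.24, limma adjusted p = 0.978). Without cKO 1 the only gene called by limma was Xist (adjusted p = 0.00143).

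**Figure D2:**
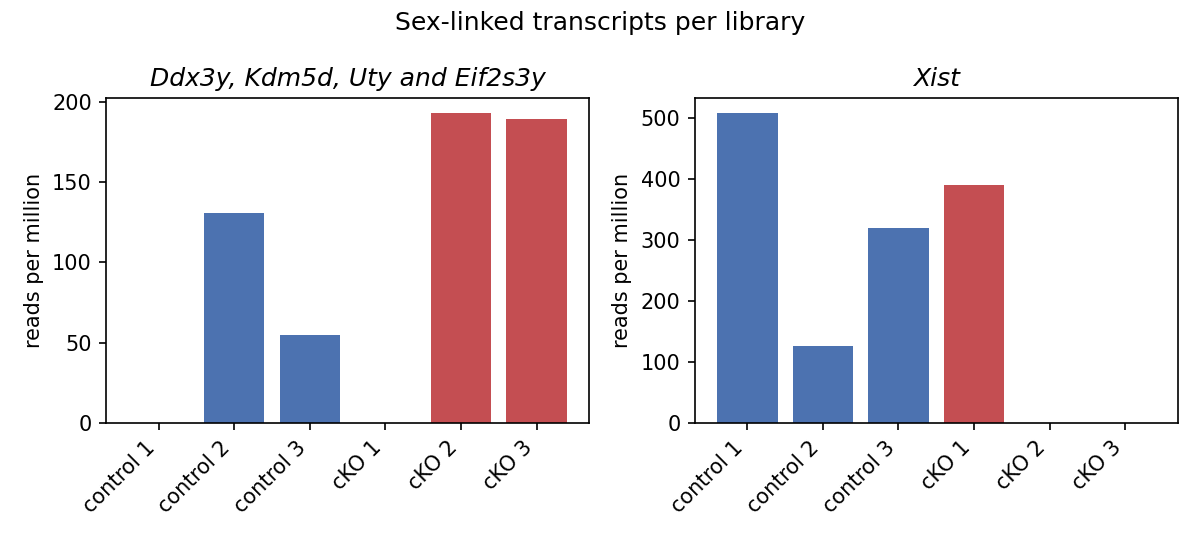
RPM (vertical axes, linear, from 0) on 4 Y-linked genes together (left) and on Xist (right) in each control (blue) and Sdhc cKO (red) library, 1 bar per library. Control 1 and cKO 1 have almost no Y-linked reads (0.048 and 0.207 RPM), cKO 2 and cKO 3 have almost no Xist, and controls 2 and 3 have both.

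After these values were seen, the comparison was fitted again with the Y-linked share of each library as a numeric covariate. This fit was added after the planned fits had called almost nothing, and 5 forms of it were tried, which called from 163 to 1194 genes. In it 826 of 12699 genes passed, 209 higher and 617 lower in cKO, and 825 of them had the same sign without the covariate. The covariate enlarged the differences. For each of the 826 genes the log2 fold change without it was divided by that with it. The median of these ratios was 0.56, and 557 genes kept at least 0.5 of theirs. The groups did not overlap at 109 of the 826. The number of calls depended on single libraries: it was 11 without cKO 1, with 1 gene shared, 89 without control 2, 202 without cKO 3 and 953 without control 1, and it was 163 with the replicate block added, with 88 shared. The 826 genes were chosen in the fit with all libraries. The median ratio of their fold changes to that fit was 0.979 without cKO 1 and 1.07 without control 2. It was 0.947 without cKO 3, 1.03 without control 1 and 0.826 with the block. As each left-out library helped to choose the genes, ratios near 1 are partly built in and do not show that the calls hold.

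Ifng and Tbx21 fell in this fit, with log2 fold changes of -0.69 (SE 0.07, limma adjusted p = 0.00344) and -0.36 (SE 0.07, 0.017). Irf4, a transcription factor of activated T cells, fell by 0.69 on the log2 scale (SE 0.06, limma adjusted p = 0.00174) and Myc by 0.38 (SE 0.08, 0.0214), although the values of both overlapped between the groups. With the replicate block added, which leaves 1 residual degree of freedom, Ifng (limma adjusted p = 0.00401) and Irf4 (0.00136) still passed. Tbx21 (-0.32, SE 0.10, 0.116) and Myc (-0.27, SE 0.09, 0.146) did not. Sdhd fell by 0.27 (SE 0.06, limma adjusted p = 0.0316), while Sdhc, at -0.17 (SE 0.08), did not pass (0.222); with the block Sdhd kept its size, at -0.27, and did not pass (SE 0.09, 0.161). Among genes whose groups did not overlap, the 10 with the largest falls were Spp1 (-1.27), Nek6 (-0.84), Ncs1 (-0.81), Lrrk1 (-0.76), Casc4 (-0.75), Slc25a13 (-0.74), Ifng, Tnfrsf8 (-0.64), Etv5 (-0.63) and Ccdc86 (-0.60). Slc25a13 encodes a mitochondrial aspartate-glutamate carrier of the malate-aspartate shuttle. The 10 with the largest rises were Mir142 (1.41), Bzrap1 (1.20), Malat1 (1.07), Col20a1 (0.97), Itgae (0.90), Dleu2 (0.84), Rasl11b (0.76), Ubxn11 (0.69), Tsc22d3 (0.55) and Eva1b (0.54). With the block, Spp1, Nek6, Ifng, Tnfrsf8, Etv5, Mir142, Bzrap1, Malat1, Dleu2 and Tsc22d3 still passed and the other 10 did not. Itgae encodes the integrin CD103 and Tsc22d3 a glucocorticoid-induced regulator. Mir142 and Bzrap1 neighbour each other and the strand setting of the counting is not given in the sources used here, so their reads may be shared and both are uncertain, as is Dleu2, which overlaps genes on the other strand.

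The 7 lists given next were picked after the results were seen, as those with the most called members. They held 73 of the 826 called genes, 8.84%, counting shared members 1 time. Of all 12699 tested genes 826 were called, 617 of them lower. Among the lists left out, Treg lineage and ribosomal protein had 2 called rises each and 0 called falls. All called members of the following lists fell: 18 of 35 S phase genes, among them Mcm2 (-0.44) and Mcm6 (-0.39), 14 of 31 ATF4 response genes, among them Asns (-0.65) and Slc7a3 (-1.25), 12 of 28 HIF targets, among them Ak4 (-1.96), Mif (-0.71) and Egln3 (-0.49), 12 of 21 glycolysis genes, among them Hk2 (-0.71) and Pfkl (-0.77), 10 of 20 nucleotide synthesis genes, among them Cad (-0.45) and Umps (-0.55), 7 of 18 NRF2 targets, among them Txnrd1 (-0.42), and 6 of 19 TCA cycle genes, among them Pcx (-0.69) and Idh3a (-0.39). With the replicate block added, 1, 1, 3, 2, 1, 0 and 1 of these falls were still called in the same order, among them Mcm2, Asns, Ak4, Mif, Hk2, Pfkl, Umps and Pcx. The list medians in that order were -0.27, -0.39, -0.38, -0.48, -0.35, -0.38 and -0.11 without the block. They were -0.24, -0.195, -0.19, -0.19, -0.24, -0.21 and -0.10 with it. Glycolysis counts summed to 145734, 270125 and 229773 in controls 1, 2 and 3 and to 119969, 264802 and 216551 in the cKO libraries. On genotype alone the glycolysis median was -0.13, so the larger fall here rests on the straight-line covariate. Leaving out cKO 1 in the fit without the block, 0 members of each of these lists were called. Leaving out control 2, the called falls were 1, 3, 2, 3, 1, 2 and 1 in the same order. With all libraries, no block and adjustment over the list alone, the falls numbered 28, 21, 18, 15, 18, 13 and 7. There was then 1 rise each in the ATF4, glycolysis and NRF2 lists. By camera 15 of 31 lists passed, 14 without the sex-linked list, which holds the genes the covariate was made from and so says nothing on genotype in this fit, and with an estimated correlation the smallest adjusted p was 0.503. With the block the calls of complexes III to V (0.815), chaperones (0.2) and cholesterol synthesis (0.96) ended. Those of Th17 lineage (0.0262), mitochondrially encoded genes (2.69e-05) and p53 targets (0.0213) were gained, all lower. With an estimated correlation the smallest camera adjusted p with the block was 0.743. Camera then works on 1 residual degree of freedom, so almost no list could pass and this value does not weigh against any. The naive and memory and interferon response lists no longer passed, and cholesterol synthesis genes passed in the opposite direction to the fit without the covariate (median 0.08, camera adjusted p = 0.037; 0.819 with an estimated correlation). Of the 29 Th1 effector genes 4 fell in this fit, Ifng, Tbx21, Lta (-0.41) and Il18rap (-0.37), the last named after its value was seen, and of these Ifng and Lta still passed with the block; without cKO 1 the median of that list was -0.00 and its camera adjusted p 0.0706. The activation list ended without control 2 (0.166), cholesterol synthesis without control 2 or cKO 3 (0.316 and 0.389), complexes III to V without control 3 or cKO 1 (0.395 and 0.193), and T cell identity without cKO 1 (0.689). Calls were gained by the mitochondrially encoded genes without control 2 (median -0.64, adjusted p = 0.000505) or cKO 3 (-0.28, 0.000464), p53 targets without cKO 3 (-0.10, 0.0158), immediate early genes without cKO 1 (-0.20, 0.0206) and B cell genes without control 2 (0.45, 0.045).

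**Figure D3:**
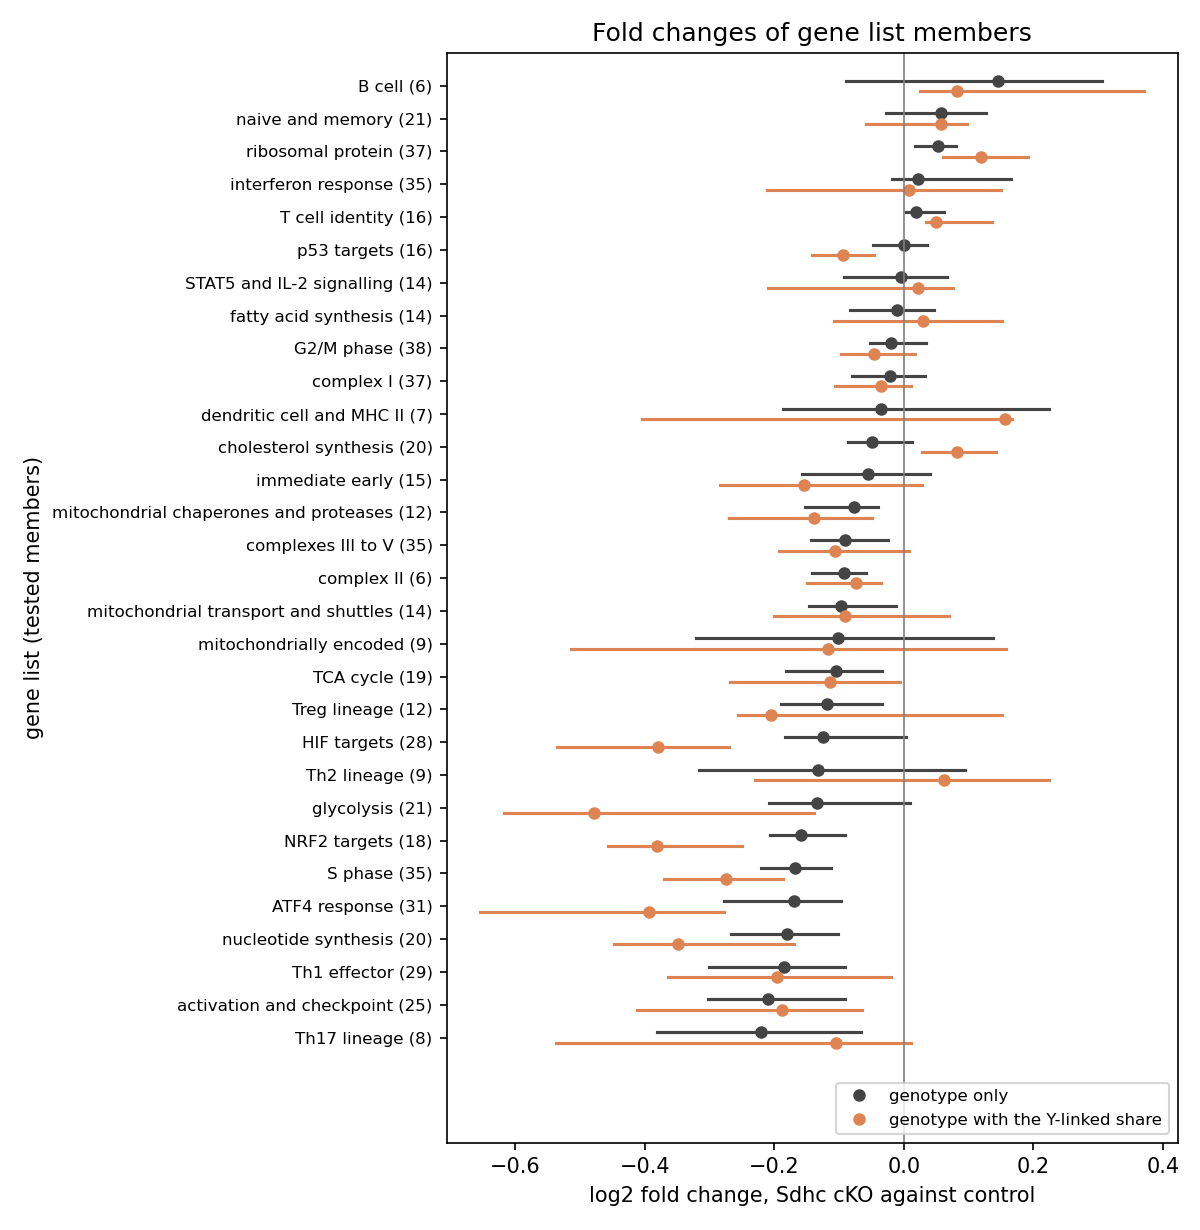
Log2 fold change of cKO against control (horizontal axis) for the tested members of each gene list (vertical axis, number of tested members in brackets); points are medians and lines span the middle 50% of the members, from the fit on genotype only (grey) and the fit with the Y-linked share as covariate (orange). The glycolysis median was -0.13 without and -0.48 with the covariate, and the Th1 effector median -0.18 and -0.20.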

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

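The covariate fits, their alternatives, edgeR with TMM, the replicate block with an estimated correlation or with the covariate, and no filter with an estimated correlation were chosen after seeing the data; the other alternatives were planned. The fit on genotype alone called 0 genes except with DESeq2 (3), array weights (1), the replicate block (1), and the covariates: the Y-linked share (826, or 670 in edgeR) and Xist (1194 linear, 475 log2); leaving out 1 library gave 0 to 1. The count of 826 genes became 475 with log2 Xist, 163 with the replicate block (88 shared, 738 lost) and 0 with no covariate, and 11 to 953 on leaving out 1 library. The fold changes of the 826 genes had a median ratio to that fit of 1.42, 0.826 and 0.56 in the first 3 of these settings. It was 0.979 without cKO 1, on genes chosen with cKO 1 included, so it does not show that the calls hold. The 11 called lists became 0 with an estimated correlation, alone, with the replicate block or with no filter, and 1 with fry, and 7 to 14 on leaving out 1 library. Medians of 19 of the 31 lists changed sign in at least 1 setting, 95 times in all. For lists called with all libraries or in the setting, these were the following. Leaving out 1 library gave -0.369 to 0.0208 for the ATF4 response, -0.30 to 0.18 for HIF targets, -0.316 to 0.0295 for NRF2 targets, -0.40 to 0.14 for glycolysis and -0.0263 to 0.0971 for ribosomal proteins, with the opposite sign without cKO 1 for all 5 and, for HIF targets, glycolysis and ribosomal proteins, also without control 2. Cholesterol synthesis went to 0.0815 with the Y-linked share (0.106 in edgeR) and to 0.111 and 0.209 with linear and log2 Xist, ribosomal proteins to -0.00373 with array weights and -0.00136 without control 2, and interferon response to -0.016 and -0.0334 with linear and log2 Xist. Targets of p53, whose camera direction was up, went to 0.103 without cKO 1 and were lower, at -0.143, with the replicate block and the covariate. Of the lists not called, Th2 lineage went from -0.13 to 0.126 without control 1, 0.0653 without cKO 3 and 0.0619 to 0.208 with the covariates. The Th1 effector call ended with linear and log2 Xist (adjusted p = 0.0596 and 0.23), and those of activation and of complexes III to V with log2 Xist (0.123 and 0.0634). The sex-linked list had a camera direction opposite to its median, which was 0.77 with the replicate block; built from the covariate's own genes, it went to -2.93 with the Y-linked share (-2.24 in edgeR) and -3.66 with linear Xist. Eif2s3y went to -4.32 with linear Xist as covariate. Without the covariate, the replicate block changed no other call than that of Ifng and those of the glycolysis, HIF, chaperone and sex-linked lists. Sdhc lay between -0.08 and -0.22 and passed in none of these settings; Ifng lay between -0.63 and -0.70. For the 83 entries of genes named with genotype alone, settings other than leaving out a library kept direction and call 1155 times, gained a call 53 times, moved an uncalled value 114 times and reversed it 1 time. Of the 92 entries named from the covariate fit 66 were called in it; they kept their call 515 times and lost it 144 times under other settings, and kept it 230 times and lost it 166 times on leaving out a library. The cause of these changes was not tested. Il2, at most 3.92 normalised counts in any library at 18144933 to 21983821 reads, was too low to compare.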

Other observations

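The tests of the covariate fit and of Sdhc, the splits for gene counts, the splits that part every pair and the term for the Y-linked share were chosen only after the results were seen; the split test of lists and the test of GC content were set up before their results. Across the 6 libraries, 2913 genes followed the Y-linked share in the fit that also held genotype, 1691 rising and 1222 falling with it (limma, adjusted p threshold 0.05). Of the glycolysis genes 17 of 21 rose and 2 fell, with a median slope of 1.02 on the log2 scale from no Y-linked reads to the highest library. Of the HIF targets 24 of 28 rose (median slope 0.95), of the ATF4 response genes 23 of 31 (0.65), of the NRF2 targets 10 of 18 (0.61), of the nucleotide synthesis genes 15 of 20 (0.40) and of the S phase genes 19 of 35 (0.29), with 0 falling in these 5 lists. The adenylate kinase gene Ak4 had a slope of 3.77 (SE 0.26, limma adjusted p = 0.000165) and the glycolytic gene Tpi1 1.95 (SE 0.18, 0.000599). Genes of cholesterol synthesis fell with the share, 13 of 20 with 0 rising (median -0.38), among them Hmgcs1 (-0.61, SE 0.14, limma adjusted p = 0.013). Ribosomal protein genes fell too, 12 of 37 with 0 rising (median -0.24), and Gzmb had a slope of -0.98 (SE 0.17, limma adjusted p = 0.00415). By camera with an estimated correlation the smallest adjusted p of any list for this term was 0.596. Both libraries with almost no Y-linked reads carry the number 1. Controls 2 and 3 had 0.678 and 0.285 of the highest share, and cKO 3 had 0.982. Yet glycolysis counts summed to 229773 in control 3 and 216551 in cKO 3, against 145734 in control 1. On the first principal component control 3 (9.96) also lay near cKO 3 (8.75) and far from control 1 (-22.47). These values did not rise in step with the share between control 3 and cKO 3, which also differ in genotype. Within the controls they did: numbers 1, 3 and 2, in order of share, had glycolysis sums of 145734, 229773 and 270125. Their values on the first principal component were -22.47, 9.96 and 24.22. The sums of cKO 1, 3 and 2, also in order of share, were 119969, 216551 and 264802. A trend with the sex of the cells cannot be told apart from whatever the libraries numbered 1 shared.

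The count of 826 genes in the fit with the Y-linked share is open to doubt. GC content is argued against as its cause, since 86.8% of the 826 genes were still called after each library's trend on GC content was removed (11988 tested genes, 94.4%, had a value). Whether cKO 1 carries the calls stays open: the difference between cKO 1 and control 1 and the genotype term from the other 4 libraries, which share no data, correlated across 12699 genes at a Pearson r of 0.2729 (Spearman 0.3337, 63.55% of genes with the same sign), between the bounds of 0.1 and 0.3 set for it; genes are not independent replicates. An earlier form of this test, the share of the 826 genes that kept their direction without cKO 1 (100%, against 76.26% of the other genes), was set aside as void, since the genes had been chosen in a fit with that library, and the present test replaced it after that outcome was known. The 3 against 3 design makes 10 splits, too few for a share under 0.05. The real split called 826 genes, 1 of the 10 splits reached that count, and the highest other split called 0. At an unadjusted p under 0.05 this fit had 3280 genes in the real split and 134 to 1747 in the others. The covariate was chosen with the real split in view. The splits also differ in their correlation with the Y-linked share, 0.404 for the real split and up to 0.942 for another, so they are not equally able to call genes. In the fit on genotype alone the real split and the highest other split both called 0, so that 10 of 10 splits gave as many.

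The 11 lists called by camera with its preset correlation were set against the same 10 splits. These are too few for a share under 0.05; the real split called 11 lists and the highest other split 15, and 6 of the 10 splits called at least 11. With an estimated correlation each of the 10 splits called 0, the real one included, so that setting cannot set the real split apart. Taking the replicate numbers as pairs, which the labels do not give, leaves 4 splits that part every pair, the real one among them. These are too few for a share under 0.05, and the comparison was chosen after the results were seen. The 3 other splits called 6, 7 and 10 lists, with 131, 104 and 115 genes at an unadjusted p under 0.05 against 445. With the replicate block they called 8, 10 and 12 lists against 15, and 3, 0 and 0 genes (limma, 376, 360 and 300 at an unadjusted p under 0.05) against 1 (1596). The other 6 splits keep a same-numbered pair together on each side. The split of control 1, cKO 1 and cKO 3 from the rest had the most genes at an unadjusted p under 0.05, 2545, and 0 after adjustment. What sets these libraries apart was not tested.

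The Sdhc count was not clearly lower in cKO. An exchange of labels between a control and a cKO library stays open: the lowest library had 0.7676 of the highest, no library of either group was clearly low, and so the count cannot show which library carries the deletion. A deletion of part of the gene that leaves a counted transcript may explain the small difference and stays open: the lower 95% limit of the log2 fold change was -0.3569, and counts per gene do not resolve exons.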
